A study of Mus musculus with 4 samples.

How the data were processed

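The data are 4 libraries of single cells (10x Genomics 3′ assay, version 3 chemistry) from the stromal vascular fraction of adipose tissue of 4 male mice, 2 double Tg and 2 single Tg, 1 of each in batch 1 and in batch 2 per the labels. The depot is not given in the sources used here. The submitters' processing notes name Cell Ranger 7.2.0, Partek (version not given) and the mouse genome mm10, with no roles given. The matrices deposited by the authors hold unnormalized UMI counts per gene symbol and barcode for 31017 symbols, here read as values in expected counts, since 0.0436% to 0.0487% of the entries in each library are not whole and end in 0.5. Features carry symbols only, so gene identity rests on the symbol; coordinates come from GENCODE M21 (GRCm38).

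Barcodes were kept with at least 300 genes, at most 20% mitochondrial UMIs and at most 10% hemoglobin UMIs. Of 8417 barcodes, 1891 had fewer genes, 1927 exceeded the hemoglobin limit and 51 the mitochondrial limit, and 6411 passed. Scrublet's automatic threshold called 21 of these (0.328%), which was read as not having worked, so the barcodes with the highest doublet scores were removed up to the expected share, 0.8% per 1000 cells: 21, 10, 18 and 38 in double Tg replicate 1, single Tg replicate 1, double Tg replicate 2 and single Tg replicate 2, 87 in all. The 6324 kept cells were scaled to 10000 UMIs and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 with seed 1 gave 29 clusters (scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, Python 3.11.15). A cluster was named when at least 3 markers of a class were among its 50 strongest genes. Marker and gene lists, comparisons and tests were fixed before the data were examined, apart from a germ cell list and the tests named in the text as chosen after seeing the data. Progenitor-like cells were clustered again in the same way.

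UMIs were summed per class and library and rounded to whole numbers, because of those entries. Double Tg was tested against single Tg in each class with at least 20 cells in every library, and in the sums of all kept cells, with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3), TMM scaling and filterByExpr. Adjusted p is Benjamini-Hochberg over the genes tested, with a threshold of 0.05, and the mouse, never the cell, is the replicate (n = 2 per genotype). Numbers of cells per class, and per subclass of progenitor-like cells, were tested in the same way for groups with at least 10 cells in 1 library, with the library's kept cells as its size. The difference between genotype effects in macrophage-like and progenitor-like cells was tested as a class by genotype term with the library as a block. Gene lists with at least 5 tested genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01. Intervals of single shares are exact binomial (Clopper-Pearson) and those of single levels exact Poisson, at 95%, for counting error only.

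Single genes were named by a rule fixed in advance. It takes genes past the threshold with the same sign in both batches and a mean log2 CPM of at least 5; where a direction has fewer than 5, the 5 with the smallest p, given as values. It adds the 3 members with the smallest p of each list that camera called and of 4 fixed lists each in progenitor-like and macrophage-like cells, and Crispld2 everywhere. Predicted genes without names are left out.

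Replicate numbers follow the batches, so they pair the libraries per the labels. Checked on the data, the correlation across genes of the double and single Tg libraries of the same number, each taken as its difference from its genotype's mean, was 0.387 in progenitor-like, 0.256 in macrophage-like, 0.297 in B-like, 0.379 in dendritic-like, 0.354 in mesothelial-like, 0.285 in NK-like and 0.468 in T-like cells and 0.448 in all cells. The batch was left out of the main test and entered as a block in an alternative. Left out, a batch effect counts as spread between replicates. A lack of calls, or fewer small p than by chance, therefore does not show that genotype differences are absent. The block in turn leaves fewer degrees of freedom to estimate the spread.

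The other alternatives, set before the data were examined, were RLE factors or library totals in place of TMM, DESeq2 1.42.0, no filter on low counts, each library left out in turn, a mitochondrial limit of 10%, doublets kept, resolutions 0.5 and 2, classes from marker scores per cell, equal numbers of cells, thinned sums, TMM or limma for shares, and an estimated correlation or fry for lists. Chosen after seeing the data were a minimum of 1000 genes, hemoglobin-rich and low-gene barcodes kept, cells above 100000 UMIs removed (15 cells), T cluster 3 and the other T clusters apart, and mixed cells removed. Mixed cells (220, 3.48% of kept) carry at least 4 markers of another lineage that are each present in at most 5% of the cells of their own class. The T-, NK- and ILC2-like classes were taken as a single lineage, so NK markers in T-like cells do not count. Neither another scaling nor library totals moved the median log2 fold change of all genes by more than 0.0667.

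What can be recovered was tested on simulated data, in which 100 genes were changed 2-fold and 100 genes 4-fold. Genes were drawn independently of each other and without a batch effect. The simulation therefore does not estimate false calls with the batch as a block in the real libraries. With the spread of the real libraries, edgeR recovered 2% of the 2-fold and 62% of the 4-fold changes in progenitor-like cells, 18% and 82% in macrophage-like, 23% and 87% in B-like, 30% and 81% in dendritic-like, 28% and 89% in mesothelial-like, 32% and 85% in NK-like and 38% and 89% in T-like cells, and 3% and 41% in all cells. With counting noise alone it recovered at least 68% and 93%. With the real spread edgeR made 4 to 12 false calls per comparison. With the batch as a block it made 4 in progenitor-like, 14 in macrophage-like, 8 in B-like, 25 in dendritic-like, 17 in mesothelial-like, 2 in NK-like and 15 in T-like cells and 31 in all cells. DESeq2 made 24 in progenitor-like cells, 64 in all cells and 1 to 8 in the other classes. For the class by genotype term the values were 3% and 66%, and a plasma-like share raised 4-fold was called in 16% of runs. Camera called a list of chaperone genes lowered 1.5-fold in all 8 comparisons with the preset correlation and in 0 with an estimated one. At the preset correlation it made 1 false call of a list in progenitor-like cells and 4 in all cells. List members were drawn without correlation between genes, so these numbers do not show how the preset correlation performs on the real lists.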

Results

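Stromal vascular cells, the non-adipocyte cells that collagenase releases from adipose tissue, were profiled by droplet single-cell RNA sequencing of transcript 3′ ends (10x Genomics), with unique molecular identifiers (UMIs). The cells came from 4 male mice aged 7 months, all given doxycycline in the diet. In 2 mice an activator under the adipocyte promoter of Adipoq was combined with a doxycycline-inducible mouse Crispld2 transgene. They are called double Tg. The other 2 mice carried the inducible transgene alone, are called single Tg and served as controls. Batch 1 and batch 2 each held 1 mouse of each genotype, numbered replicate 1 and replicate 2. The question behind the design, as the series title puts it, is what CRISPLD2, a secreted protein, does to adipocyte function. In the order double Tg replicate 1, single Tg replicate 1, double Tg replicate 2, single Tg replicate 2, the deposited tables held 2041, 1311, 2325 and 2740 barcodes with 38575981.5, 25974625, 36682743.5 and 37268253.5 UMIs. After filtering, 1617, 1097, 1482 and 2128 cells remained, with median depths of 17117, 18558, 12680 and 10299 UMIs per cell.

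The 6324 kept cells formed 29 clusters, which fixed markers grouped into 14 classes, each called "like" the cell type whose markers it carries. Progenitor-like stromal cells (clusters 0, 1, 2 and 10) were the largest class with 2246 cells. T-like cells (clusters 3, 9, 11, 14 and 16) numbered 1144 and macrophage-like cells (clusters 7, 12, 13 and 19) 763. Dendritic-like cells (clusters 5, 15, 25 and 27) numbered 562, mesothelial-like cells (clusters 4 and 23) 421, B-like cells (clusters 6 and 21) 415 and NK-like cells (cluster 8) 279. Plasma-like (cluster 17, 122 cells), ILC2-like (cluster 18, 112), proliferating (cluster 20, 95), mast-like (cluster 22, 61), epididymal-like (cluster 24, 46), neutrophil-like (cluster 26, 35) and lymphatic endothelial-like cells (cluster 28, 23) were too few in at least 1 library for a gene-level test. Clusters 10, 13 and 23 were the shallowest, with medians of 1102, 968 and 845 UMIs per cell. Clusters 22, 24 and 27, the last dendritic-like, followed with 1537, 1843 and 2893, and clusters 17 and 26 with 3855 and 4251.5. Below, log2 fold changes are double Tg minus single Tg, n = 2 mice per genotype. Their standard errors are approximate: the absolute log2 fold change divided by the square root of the edgeR F statistic. Levels of single genes are in CPM on the TMM scale unless stated otherwise. With 2 mice against 2, an exact two-sided permutation test cannot go below p = 0.333.

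Crispld2 (chromosome 8, 119992438 to 120052793 in GRCm38, protein coding, up to 15 exons) was measured first, since it is the gene of the transgene. In all kept cells together it reached 73.7 CPM of raw UMIs in double Tg replicate 1, 65.2 in single Tg replicate 1, 66.8 in double Tg replicate 2 and 105 in single Tg replicate 2. Progenitor-like cells held the most, with 158 and 123 CPM in the double Tg libraries and 107 and 246 CPM in the single Tg libraries. Mesothelial-like cells followed with 73.8 and 85.6 CPM against 73.8 and 111 CPM. In T-, B-, dendritic- and macrophage-like cells no library exceeded 3.48 CPM, and NK-like cells held 0 UMIs, which allows at most 4.14, 10.1, 5.50 and 2.96 CPM in the 4 libraries. Crispld2 was therefore not higher in double Tg cells by any test run: the log2 fold change was -0.24 ± 0.28 over all cells, -0.32 ± 0.40 in progenitor-like cells and -0.29 ± 0.23 in mesothelial-like cells (edgeR adjusted p = 1.0, 1.0 and 0.987). The sign rests on single Tg replicate 2: without it the values were 0.17, 0.42 and 0.04. Stromal vascular cells hold few adipocytes, and the labels do not say whether the transgene transcript carries the 3′ end that this assay reads, so the lack of a difference checks neither the labels nor the induction.

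**Figure D1:**
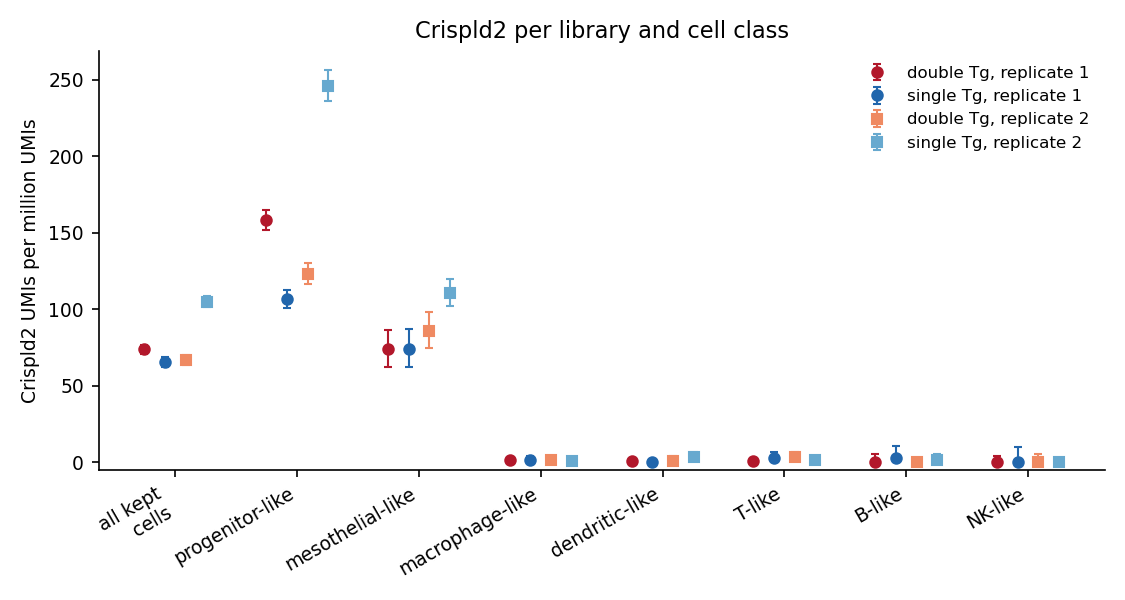
Crispld2 in CPM of raw UMIs (vertical axis) in all kept cells and in 7 cell classes (horizontal axis), 1 point per library with its exact 95% Poisson interval, which covers counting error only. Progenitor-like cells reach 246 CPM in single Tg replicate 2 and 107 to 158 CPM in the other libraries, and the immune classes lie near 0.

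The composition of the fraction was compared next. Progenitor-like cells made up 33.7% ± 2.35 (SD, n = 2) of double Tg cells and 39.7% ± 10.5 of single Tg cells. Macrophage-like cells made up 15.9% ± 9.56 and 8.87% ± 3.57, 1.99 and 1.45 times the single Tg share in batches 1 and 2. Mesothelial-like cells made up 4.74% ± 2.07 and 7.74% ± 3.60, and T-like cells 15.9% ± 2.03 and 18.9% ± 6.17. Dendritic-like cells made up 9.99% ± 3.45 and 8.35% ± 2.76, B-like cells 6.14% ± 4.39 and 6.64% ± 2.04, and NK-like cells 4.21% ± 0.425 and 4.14% ± 1.99. Plasma-like cells, which carry immunoglobulin and Jchain transcripts, differed most: 1.11% (exact binomial 95% interval 0.661 to 1.75) and 5.87% (4.73 to 7.19) in double Tg against 0.182% (0.0221 to 0.657) and 0.705% (0.395 to 1.16) in single Tg. Among the scarcer classes, ILC2-like cells made up 1.42% ± 0.0876 and 1.82% ± 1.28, proliferating cells 1.81% ± 0.938 and 1.20% ± 0.105, and mast-like cells 1.19% ± 0.0635 and 0.718% ± 0.114. Epididymal-like cells made up 0.534% ± 0.581 and 0.749% ± 0.802, neutrophil-like cells 0.596% ± 0.557 and 0.464% ± 0.141, and lymphatic endothelial-like cells 0.326% ± 0.111 and 0.305% ± 0.432. Intervals cover counting error only.

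No class share differed between genotypes by the edgeR test on cell numbers at clustering resolution 1: 0 of 14 classes passed, 1 (plasma-like) had an unadjusted p under 0.05, and limma also called 0. At resolution 0.5 the same edgeR test called the plasma-like share. The plasma-like share had a fold of 7.27 (6.11 and 8.33 in batches 1 and 2; edgeR adjusted p = 0.0843, exact permutation p = 0.333), and the adjusted p of the other 13 classes was 0.984. The plasma-like cells were not alike in depth: their median was 1472 UMIs in double Tg replicate 2 and 24717, 33357 and 44432 UMIs in double Tg replicate 1, single Tg replicate 1 and single Tg replicate 2. Counting only cells with at least 1000 genes, a limit set after seeing the data, the plasma-like share was 0.977% and 2.60% in double Tg and 0.103% and 0.763% in single Tg.

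**Figure D2:**
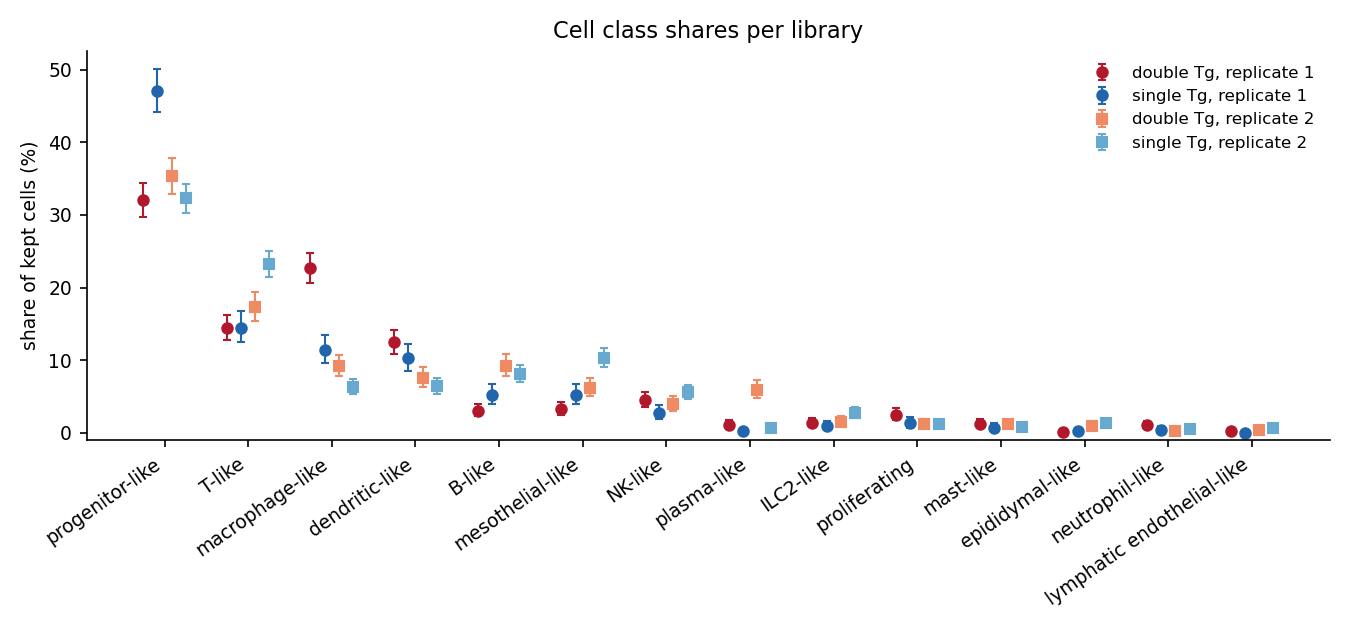
Share of kept cells in percent (vertical axis) for each of the 14 cell classes (horizontal axis), 1 point per library with its exact binomial 95% interval, which covers counting error only. Plasma-like cells reach 5.87% in double Tg replicate 2 and at most 1.11% in the other libraries. In every class but mast-like cells, the replicates of at least 1 genotype lie further apart than the means of the genotypes do.

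Within the progenitor-like class, 11 subclusters were compared. Preadipocyte-like cells (subcluster 3, by markers of committed adipocyte precursors) made up 31.3% (27.3 to 35.5) and 13.2% (10.4 to 16.4) of progenitor-like cells in double Tg replicates 1 and 2, against 6.58% (4.60 to 9.07) and 4.08% (2.73 to 5.84) in single Tg. The name rests on 5 markers among the subcluster's 50 strongest genes, with 0 among the top 10. Dpp4-like cells (subclusters 1, 5 and 7), the earlier interstitial progenitors, made up 28.4% and 38.6% against 42.6% and 12.2%. Subcluster 2 had 2 preadipocyte markers among its 50 strongest genes, Fabp4 among the top 10, and missed the 3 needed for a name. It held 32.9% of progenitor-like cells in single Tg replicate 2 and 2.90%, 5.42% and 9.35% in double Tg replicate 1, single Tg replicate 1 and double Tg replicate 2. The fold of the preadipocyte-like share was 4.17 (4.76 and 3.23 in batches 1 and 2; edgeR adjusted p = 0.667, exact permutation p = 0.333). In all, 0 of 9 subclasses passed by edgeR, 0 had an unadjusted p under 0.05, and limma called 0.

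In progenitor-like cells, from which adipocytes form, the clearest difference was Saa3, an acute-phase serum amyloid gene (chromosome 7, 46711998 to 46715700). It had 69.8 and 39.7 CPM in double Tg replicates 1 and 2 against 6.55 and 9.40 CPM in single Tg, a log2 fold change of 2.79 ± 0.35. It did not pass by edgeR (adjusted p = 1.0) but did by DESeq2 (adjusted p = 8.2e-09). S100a4, a calcium-binding protein of motile fibroblasts, had 64.6 and 54.7 CPM against 28.0 and 24.3 CPM, and Angptl4, an inhibitor of lipoprotein lipase, 147 and 186 CPM against 96.0 and 104 CPM. Inmt, a methyltransferase of indoles, had 132 and 176 CPM against 306 and 498 CPM. Sirt1, a deacetylase, had 41.3 and 33.1 CPM against 69.3 and 68.3 CPM, and Chka, a choline kinase, 40.5 and 33.6 CPM against 69.7 and 68.4 CPM. Adam19, Cdk6 and Efnb1 had log2 fold changes of 0.78 ± 0.21, 0.71 ± 0.21 and 0.58 ± 0.20, and Plcxd3 and Rtl4 of -0.86 ± 0.19 and -1.63 ± 0.36. All of these had the same sign in both batches, which apart from Saa3 was a condition for naming them and not a result.

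Of the 19 tested genes of adipogenesis and lipid storage, 0 passed over all genes and 0 adjusted over the list alone, and 12 had negative log2 fold changes (median -0.04; camera adjusted p = 0.805, and adjusted p = 0.984 with an estimated correlation). Among them Dgat2, which completes triglycerides, had -1.17 ± 0.35, Klf15 -0.82 ± 0.43 and Plin2, a lipid droplet coat protein, 0.60 ± 0.28. Of the 20 fibrillar matrix genes 0 passed either way and 14 were positive (median 0.07; camera adjusted p = 0.425, and adjusted p = 0.984 with an estimated correlation). Eln (elastin) had -0.88 ± 0.36, Lox (lysyl oxidase) -0.76 ± 0.39 and Postn (periostin) 0.45 ± 0.24. Of 19 inflammatory genes 1, Saa3, passed when adjusted over the list alone; Ccl5 had -1.85 ± 0.74 and Il1b 3.06 ± 1.27. Il1b rested on double Tg replicate 2, without which its value was -0.57, and on mixed cells, without which it was -0.096. The acute-phase gene Lcn2 had 1.37 ± 0.61 and the complement gene C2 -0.56 ± 0.43, the latter 0.17 without single Tg replicate 2.

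Heat shock genes, which encode protein-folding chaperones, fell as a group in progenitor-like cells: 10 of 10 had negative log2 fold changes, with a median of -0.41 (-0.47 and -0.41 in batches 1 and 2; camera adjusted p = 4.1e-05, and adjusted p = 0.984 with an estimated correlation). Hsph1 had -0.66 ± 0.22, Hsp90aa1 -0.62 ± 0.26 and Hspd1 -0.40 ± 0.22, and 0 of the 10 passed by themselves. The list's adjusted p was 0.110 without double Tg replicate 1 and 0.590 without single Tg replicate 2. Class II antigen presentation genes rose as a group, with 6 of 6 positive and a median of 0.78 (camera adjusted p = 4.1e-05, and adjusted p = 0.984 with an estimated correlation; 0.0573 without double Tg replicate 2). Cells that also carried markers of another lineage, called mixed cells below, held 23.3% and 66.1% of these UMIs in double Tg and 7.84% and 27.6% in single Tg, and without them the list's adjusted p was 0.721. Cd74, H2-Aa and H2-Ab1 had 1.18 ± 0.41, 0.95 ± 0.37 and 0.86 ± 0.33. With the predicted doublets kept, Cd74 and H2-Aa turned to -0.13 and -0.22. Camera called 8 of 43 lists in all (5 higher, 3 lower; 0 with an estimated correlation). The other 6 were B-cell markers, proliferation, complement and acute phase, and Dpp4 progenitor markers among the higher ones, and cholesterol synthesis and muscle genes among the lower ones. The Dpp4 list had medians of -0.41 and 1.34 in batches 1 and 2 and the complement list -0.29 and 0.19, so neither was higher in both. The B-cell list could not be tested without mixed cells. With the batch as a block the complement and acute phase list was no longer called (adjusted p = 0.0787) and the unfolded protein response was called lower (0.0441).

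Of 14045 genes tested in progenitor-like cells, edgeR called 0 at an adjusted p under 0.05; 426 had an unadjusted p under 0.05, against 702 by chance, and DESeq2 called 3: Saa3 higher, and Svip (-6.08) and Sox6 (-3.91), both chosen after their values were seen, lower. In simulated data with the spread of the real libraries DESeq2 made 24 false calls here. The largest cluster of the class differed between libraries: cluster 0 with 51.0% in double Tg replicate 1, cluster 1 with 43.9% and 39.9% in single Tg replicate 1 and double Tg replicate 2, and cluster 2 with 52.8% in single Tg replicate 2. Without single Tg replicate 1 or 2 edgeR called 399 and 1218 genes.

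Macrophages are the main immune cells of adipose tissue. In macrophage-like cells Pecam1, an adhesion molecule, had 20.1 and 18.1 CPM in double Tg replicates 1 and 2 against 65.7 and 58.0 CPM in single Tg, and Mir155hg, the host of an inflammatory microRNA, 57.5 and 68.3 CPM against 147 and 157 CPM. Pde4c had -2.04 ± 0.28. Chil3, a chitinase-like protein of monocytes and alternatively activated macrophages, had 50.04 and 84.0 CPM against 14.4 and 18.8 CPM (1.99 ± 0.32), and Sirpb1c 73.4 and 82.9 CPM against 39.8 and 29.5 CPM. The antibody genes Jchain, Ighm and Igkc had 3.59 ± 0.57, 3.05 ± 0.56 and 4.03 ± 0.81, but 1 cell held 89.9% and 95.9% of the Igkc UMIs in the double Tg libraries. Ighm was at -0.15 without mixed cells. Ikzf2, a top marker of T cluster 16, had 13.6 and 7.00 CPM against 72.2 and 65.5 CPM (-2.63 ± 0.31), and Rora, a nuclear receptor, 30.1 and 21.6 CPM against 78.2 and 99.3 CPM (-1.74 ± 0.25). Without mixed cells, which carry most T markers of this class, Ikzf2 was too low to be tested and Rora was at -0.57, while Pecam1 was at -1.96 and Pde4c at -2.18.

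The mix of macrophage clusters was not the same in the libraries. Cluster 12, which has Chil3 and Sirpb1c among its 10 top marker genes, made up 21.8% (exact binomial 95% interval 17.7 to 26.4) and 36.0% (28.0 to 44.7) of the class in double Tg replicates 1 and 2 against 15.2% (9.41 to 22.7) and 21.5% (14.9 to 29.4) in single Tg. Cluster 19, with the resident macrophage genes Pf4, Folr2 and Cbr2 among its top markers, made up 9.54% (6.73 to 13.01) and 14.7% (9.22 to 21.8) against 24% (16.8 to 32.5) and 17.8% (11.7 to 25.3). Of these pairs only that of cluster 19 in batch 1 had intervals apart. Clusters 7 (42.0% and 33.8% against 39.2% and 41.5%) and 13 (26.7% and 15.4% against 21.6% and 19.3%) went opposite ways in the 2 batches. The shares of clusters were not tested. Genes of these clusters were compared over the whole class and not within clusters.

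Lipid-associated macrophage genes went both ways: Mmp12, an elastase, had 169 and 200 CPM in double Tg against 22.9 and 78.9 CPM in single Tg. Gpnmb had 2.18 and 2.92 CPM against 28.4 and 5.37 CPM and Fabp5 58.8 and 61.3 CPM against 239 and 74.6 CPM. Adjusted over the list alone, 1 of its 13 genes passed higher and 2 lower. Of the resident macrophage genes, Mrc1 had -0.27 ± 0.25, Gas6 -0.47 ± 0.32 and Cd163 -0.90 ± 0.48 (0.32 without single Tg replicate 1). The class II genes Ciita, H2-DMa and H2-Eb1 had 0.56 ± 0.24, -0.21 ± 0.22 and -0.18 ± 0.26. Monocyte markers rose as a group, with 9 of 15 positive and a median of 0.38 (camera adjusted p = 0.0292, and adjusted p = 0.735 with an estimated correlation). Hp had 1.66 ± 0.39 and Cd300e -2.61 ± 0.63. The adjusted p of this list was 0.372 without single Tg replicate 1, 0.201 without double Tg replicate 2 and 0.128 without mixed cells.

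Heat shock genes fell as a group in macrophage-like cells too, 9 of 10 negative with a median of -0.45 (-0.15 and -0.81 in batches 1 and 2; camera adjusted p = 0.00491, and adjusted p = 0.735 with an estimated correlation). Hspa1a, Hspa1b and Dnajb1 had -0.53 ± 0.23, -0.51 ± 0.24 and -0.49 ± 0.21. The list's adjusted p was 0.596 without double Tg replicate 2 and 0.133 without single Tg replicate 2. Inflammatory genes fell as a group, 16 of 19 negative with a median of -0.26 (camera adjusted p = 0.0476, and adjusted p = 0.735 with an estimated correlation), and 0 passed adjusted over the list alone. Ptgs2 (cyclooxygenase) had -0.73 ± 0.19, Tnfaip3 -0.48 ± 0.21 and Il6 -0.49 ± 0.24, the last 0.052 with classes from marker scores. This list turned to the higher side without double Tg replicate 1 (0.321) and was at 0.707 without single Tg replicate 2. Immediate early genes fell too, 13 of 16 negative with a median of -0.21 (camera adjusted p = 0.0476, and adjusted p = 0.735 with an estimated correlation), and 0 passed adjusted over the list alone. Klf4 had -0.78 ± 0.21, Socs3 -0.61 ± 0.27 and Jun -0.39 ± 0.22. The list was at 0.115, 0.130 and 0.0747 without double Tg replicate 1, single Tg replicate 1 and single Tg replicate 2. The markers of T cells, another cell type, fell most: 15 of 15 were negative with a median of -1.68, and 14 passed when adjusted over the list alone (camera adjusted p = 8.1e-26, and adjusted p = 0.735 with an estimated correlation). Mixed cells made up 5.72% and 3.68% of macrophage-like cells in double Tg and 9.60% and 13.3% in single Tg. They held between 82.3% and 94.7% of the T-marker UMIs in each library. T markers are among those that define mixed cells here, so a high share was favoured by the definition.

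Of 9607 genes tested in macrophage-like cells, edgeR called 0; 595 had an unadjusted p under 0.05, against 480 by chance, the smallest adjusted p was 0.105, and DESeq2 called 21 (3 higher, 18 lower). Camera called 7 of 35 lists (1 higher, 6 lower; 0 with an estimated correlation), the others being lower dendritic-marker and proliferation lists. The dendritic-marker list had medians of 0.11 and -0.54 in batches 1 and 2. Without mixed cells it was at 0.606 and the proliferation list could not be tested. With the batch as a block the glucocorticoid response list was called lower as well (adjusted p = 0.0241). EdgeR called 20, 67 and 31 genes without double Tg replicate 1, single Tg replicate 1 and single Tg replicate 2, and 0 without double Tg replicate 2.

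In T-like cells 2 genes fell, both of cytotoxic lymphocytes. Gzma (granzyme A, chromosome 13, 113093825 to 113100981) had 1.86 and 4.32 CPM in double Tg replicates 1 and 2 against 88.6 and 58.1 CPM in single Tg, a log2 fold change of -4.56 ± 0.39 (edgeR adjusted p = 0.00586). Klra8, an NK-cell receptor (chromosome 6, 130115226 to 130129898), had 0 against 96 raw UMIs, at least 27.9-fold lower with the floor of 3 counts over the group (edgeR adjusted p = 0.0311). It belongs to a family of near-identical genes between which reads can be split, so its identity is uncertain. Both rest on few cells: 1 cell held 85.5% and 61.0% of the Gzma UMIs in the single Tg libraries, 4 and 15 cells held any, and 3 cells in each held all Klra8 UMIs. Without mixed cells edgeR called 0 genes. The Gzma value was then -3.60 (adjusted p = 0.408), as the 1 cell with 85.5% of the UMIs was a mixed cell. No Klra8 UMI lay in mixed cells, and its edgeR adjusted p was 0.0910 without them. Both genes are among the top markers of the NK-like cluster 8. NK markers do not count toward mixed cells in the T-like class. Removing mixed cells therefore cannot show whether NK cells placed in this class, or droplets holding a T and an NK cell, carry the 2 genes.

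The genes with the next smallest p in T-like cells were Frmd4a (122 and 88.9 CPM in double Tg against 41.5 and 26.9 CPM in single Tg), and Tnfsf11, the ligand RANKL (239 and 274 CPM against 121 and 112 CPM), on the higher side. P2rx7, an ATP receptor (77.8 and 79.0 CPM against 36.0 and 23.6 CPM), Auts2 and Pik3ap1 followed. On the lower side were Setbp1 (38.7 and 31.9 CPM against 70.2 and 99.5 CPM), Tnfrsf9, the receptor 4-1BB (35.4 and 37.1 CPM against 75.1 and 73.4 CPM), Mir155hg and Ptger4. Tnfsf11 and Auts2 turned to -0.22 and -0.80 among T clusters other than cluster 3, and Setbp1 and Ptger4 to 0.63 and 0.37 within cluster 3. Cluster 3, which carries transcripts of the gamma-delta T-cell receptor, made up 53.4% and 43.2% of T-like cells in double Tg and 34.6% and 24.3% in single Tg.

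Interferon response genes fell as a group in T-like cells, 13 of 13 negative with a median of -0.71 (-0.54 and -0.41 in batches 1 and 2; camera adjusted p = 3.5e-08, and adjusted p = 0.837 with an estimated correlation). Igtp, Irgm1 and Isg15 had -0.87 ± 0.21, -1.19 ± 0.33 and -0.71 ± 0.29, and 2 of the 13 passed when adjusted over the list alone. Heat shock genes fell as a group, 9 of 10 negative with a median of -0.39 (camera adjusted p = 0.00145, and adjusted p = 0.837 with an estimated correlation; 0.0603 without single Tg replicate 1). Hsph1, Dnaja1 and Hspd1 had -0.48 ± 0.21, -0.47 ± 0.20 and -0.41 ± 0.18. NK markers fell as a group too, 11 of 14 negative with a median of -0.56 (camera adjusted p = 5.5e-14, and adjusted p = 0.837 with an estimated correlation). Gzma and Klra8 are members of that list, as is Ncr1 (-2.70 ± 0.82). The T-cell markers Cd6, Lef1 and Trac had -0.67 ± 0.19, -0.62 ± 0.21 and -0.51 ± 0.21.

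EdgeR called 2 of 10089 genes in T-like cells, 0 higher and 2 lower, and DESeq2 called 9 (7 higher, 2 lower). Under the batch block edgeR called 302 (172 higher, 130 lower). The same fit made 15 false calls in simulated data, which held no batch effect, so that number does not estimate the false calls among the 302. Camera called 4 of 31 lists without the block (0 higher, 4 lower; 0 with an estimated correlation), of which T-cell markers were the fourth. With it the TGF-beta response and inflammatory lists were called lower as well (adjusted p = 0.0322 and 0.00155). Without double Tg replicate 1, single Tg replicate 1, double Tg replicate 2 and single Tg replicate 2 edgeR called 9, 235, 1 and 81 genes.

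In mesothelial-like cells, which line the surface of fat depots, genes of TGF-beta response fell as a group: 11 of 12 were negative, with a median of -0.66 (-0.20 and -0.73 in batches 1 and 2; camera adjusted p = 1.3e-09, and adjusted p = 0.300 with an estimated correlation). Adjusted over the list alone, 5 passed. Ctgf, a matricellular growth factor, had 90.7 and 65.9 CPM in double Tg against 184 and 227 CPM in single Tg (-1.40 ± 0.22), Acta2 (smooth muscle actin) -0.81 ± 0.25 and Smad7 -0.82 ± 0.23. The growth arrest genes Gadd45b and Gadd45g had -1.09 ± 0.17 and -1.33 ± 0.23, Bdnf -1.03 ± 0.20, Fosl1 -0.90 ± 0.17 and Igfbp2, an IGF-binding protein, -2.09 ± 0.41. Interferon response genes fell as a group, 17 of 19 negative with a median of -0.75 (-0.59 and -0.74; camera adjusted p = 1.5e-06, and adjusted p = 0.470 with an estimated correlation; 0.144 without single Tg replicate 2). Ifi44 and Cxcl10 had -1.80 ± 0.39 and -1.74 ± 0.45. Saa3, higher in the double Tg progenitor-like cells, had 4.99 and 2.37 CPM against 12.2 and 20.1 CPM here (-2.22 ± 0.46). Heat shock genes were not called (7 of 10 negative, median -0.09; camera adjusted p = 0.25).

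Class II antigen presentation genes had positive values in mesothelial-like cells: Cd74, H2-Eb1 and H2-Aa had 3.58 ± 0.43, 3.41 ± 0.43 and 3.27 ± 0.42. The list rose as a group with 6 of 6 positive and a median of 3.32 (camera adjusted p = 1.3e-36, and adjusted p = 0.300 with an estimated correlation). The dendritic-cell genes Ccr7, Wdfy4 and Irf8 had 5.82 ± 0.67, 5.37 ± 0.61 and 4.23 ± 0.54, the macrophage gene Mrc1 3.26 ± 0.42, and Etv6 and Cd44 1.41 ± 0.19 and 1.62 ± 0.23. Without mixed cells Etv6 and Cd44 were at 0.13 and 0.29. Mixed cells held 93.5% and 92.2% of the class II UMIs in the double Tg libraries and 0% and 61.3% in the single Tg libraries. Of 10939 genes edgeR called 0; 608 had an unadjusted p under 0.05, against 547 by chance, the smallest adjusted p was 0.0756, and DESeq2 called 41 (33 higher, 8 lower). With the batch as a block edgeR called 40 (29 higher, 11 lower), and made 17 false calls in simulated data without a batch effect. Camera called 21 of 36 lists with the block in place of 19 (4 higher, 15 lower, and 0 with an estimated correlation). The 2 lists added were mesothelial and T-cell markers, both lower (adjusted p = 0.0263 and 0.0219). Without double Tg replicate 1, single Tg replicate 1, double Tg replicate 2 and single Tg replicate 2 edgeR called 41, 110, 34 and 52 genes, and camera called 12 lists without mixed cells.

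In dendritic-like cells Lpl (lipoprotein lipase) had 12.1 and 18.0 CPM in double Tg against 61.3 and 77.1 CPM in single Tg (-2.25 ± 0.26), and Il1rl1 (the IL-33 receptor) 62.6 and 60.4 CPM against 215 and 155 CPM. Frmd5 had -2.44 ± 0.33, Inpp4b -1.56 ± 0.22 and Cd69 -1.33 ± 0.20. Fos, Krt80, Klri1 and Pid1 had 0.89 ± 0.18, 1.05 ± 0.18, 1.02 ± 0.18 and 0.94 ± 0.21. Class II genes rose as a group, 7 of 7 positive with a median of 0.37 (0.36 and 0.32 in batches 1 and 2; camera adjusted p = 0.00215, and adjusted p = 0.387 with an estimated correlation). Ciita, H2-Ab1 and H2-Eb1 had 0.47 ± 0.21, 0.42 ± 0.20 and 0.34 ± 0.17. Heat shock genes fell as a group, 10 of 10 negative with a median of -0.37 (camera adjusted p = 2.3e-04, and adjusted p = 0.387 with an estimated correlation). TGF-beta response genes did so too, 6 of 7 negative with a median of -0.32 (camera adjusted p = 0.00108, and adjusted p = 0.387 with an estimated correlation). There Pmepa1 and Smad7 had -1.08 ± 0.22 and -0.74 ± 0.18, and the list was at 0.0563 without single Tg replicate 2. Interferon response genes fell as a group, 8 of 13 negative with a median of -0.22 (camera adjusted p = 0.0295, and adjusted p = 0.658 with an estimated correlation). They turned to the higher side without double Tg replicate 1 (0.337), and were at 0.792 without single Tg replicate 2. Markers of other cell types moved with the genotype here too. ILC2 markers fell, 5 of 5 negative with a median of -1.59 (camera adjusted p = 2.1e-14, and adjusted p = 0.387 with an estimated correlation; 1.9e-07 without mixed cells). Il1rl1 is among the 10 top markers of the ILC2-like cluster and of T cluster 16, and Frmd5 of T cluster 16. Without mixed cells, however, Il1rl1 was at -1.39 and Frmd5 at -2.08. At resolution 2 Frmd5 is also among the 10 top markers of a dendritic-like cluster. That cluster held 10 and 17 cells in double Tg replicates 1 and 2 and 31 and 31 in single Tg. The source of these differences was not tested. B-cell markers (13 of 14 negative, median -1.95; camera adjusted p = 8.8e-19, and adjusted p = 0.387 with an estimated correlation) fell. T-cell markers fell too (21 of 21 negative, median -0.75; camera adjusted p = 5.6e-12, and adjusted p = 0.469 with an estimated correlation; 3.2e-06 without mixed cells). Mixed cells made up 4.48% and 7.14% of the class in double Tg and 12.4% and 10.3% in single Tg.

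Of 10170 genes tested in dendritic-like cells edgeR called 0; 743 had an unadjusted p under 0.05, against 508 by chance, the smallest adjusted p was 0.198, and DESeq2 called 41 (4 higher, 37 lower). Camera called 12 of 34 lists (2 higher, 10 lower; 0 with an estimated correlation), and a 13th, mitochondrially encoded genes, with the batch as a block (adjusted p = 0.0278). Without double Tg replicate 1, single Tg replicate 1, double Tg replicate 2 and single Tg replicate 2 edgeR called 5, 163, 47 and 186 genes.

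In NK-like cells Serpinb9b, a granzyme inhibitor, had 39.7 and 105 CPM in double Tg against 3.50 and 24.4 CPM in single Tg, and Sh2d1a, a signalling adaptor, 188 and 149 CPM against 94.6 and 74.1 CPM. Ezh1, Zfp512 and Ppp3cc had 1.68 ± 0.40, 1.04 ± 0.27 and 0.99 ± 0.27. H2-Eb1, Pak1, Arhgap6, Pmepa1 and Tmem2 had -1.83 ± 0.50, -1.44 ± 0.41, -1.66 ± 0.48, -1.56 ± 0.46 and -0.91 ± 0.28. Heat shock genes fell as a group, 9 of 9 negative with a median of -0.34 (camera adjusted p = 5.2e-05, and adjusted p = 0.523 with an estimated correlation). TGF-beta response genes fell too, 6 of 6 negative with a median of -0.69 (camera adjusted p = 5.2e-05, and adjusted p = 0.523 with an estimated correlation), and 3 of them passed when adjusted over the list alone. Without single Tg replicate 2 the second list was at 0.208. NK markers rose as a group, 12 of 16 positive with a median of 0.28 (camera adjusted p = 0.0244, and adjusted p = 0.523 with an estimated correlation). Klrb1c, Ncr1 and Prf1 (perforin) had 0.78 ± 0.29, 0.51 ± 0.24 and 0.50 ± 0.25. Class II genes fell, 4 of 5 negative with a median of -1.69 (camera adjusted p = 0.00245, and adjusted p = 0.568 with an estimated correlation), but the medians were 0.84 and -2.40 in batches 1 and 2. Without single Tg replicate 2 that list turned to the higher side (0.384). In that library 3 of 118 NK-like cells were mixed with B or plasma cells, against 0 of 58 in double Tg replicate 2. Without mixed cells the list could not be tested and Cd74 was at 0.61. The adjusted p of the NK marker list was 0.0615, 0.117 and 0.199 without double Tg replicate 1, double Tg replicate 2 and single Tg replicate 2.

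Of 6868 genes tested in NK-like cells edgeR called 0; 277 had an unadjusted p under 0.05, against 343 by chance, and DESeq2 called 0. With the batch as a block edgeR called 24 (13 higher, 11 lower), and made 2 false calls in simulated data without a batch effect. In the real libraries 481 genes had an unadjusted p under 0.05 with the block, above the number by chance. Among the 24 were Serpinb9b, Sh2d1a and Ezh1 higher and the heat shock genes Hsph1, Dnaja1 and Hsp90aa1 lower. The B-cell and class II genes Igkc, Cd74 and Ighm were also called lower (adjusted p = 8.5e-08, 2.8e-07 and 0.0389), Cd74 with opposite signs in the batches. Camera called 7 of 21 lists (2 higher, 5 lower; 0 with an estimated correlation). Without double Tg replicate 1, single Tg replicate 1, double Tg replicate 2 and single Tg replicate 2 edgeR called 20, 1, 52 and 2 genes.

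In B-like cells heat shock genes fell as a group, 10 of 10 negative with a median of -0.60 (-0.42 and -0.68 in batches 1 and 2; camera adjusted p = 7.5e-10, and adjusted p = 0.655 with an estimated correlation). Adjusted over the list alone, 7 passed. Hspb1, Hsph1 and Dnaja1 had -1.99 ± 0.51, -0.70 ± 0.23 and -0.58 ± 0.22. Immediate early genes fell as a group, 15 of 15 negative with a median of -0.49 (-0.09 and -0.55; camera adjusted p = 3.7e-05, and adjusted p = 0.658 with an estimated correlation). Klf4, Atf3 and Nr4a1 had -0.73 ± 0.28, -0.73 ± 0.29 and -0.62 ± 0.27. Without single Tg replicate 2 that list turned to the higher side (adjusted p = 0.792). Mitochondrially encoded genes fell as well, 13 of 13 negative with a median of -0.21 (camera adjusted p = 0.0321, and adjusted p = 0.688 with an estimated correlation), and turned to the higher side without single Tg replicate 1 (0.391) and double Tg replicate 2 (0.936). TGF-beta response genes fell as a group, 5 of 6 negative with a median of -0.35 (camera adjusted p = 0.0321, and adjusted p = 0.658 with an estimated correlation). This list was at 0.0617 without double Tg replicate 1 and 0.171 without double Tg replicate 2, and on the higher side without single Tg replicate 2 (0.935). Among single genes, Abtb2, Dgkh, Maml3, Abcg1 (a cholesterol exporter) and Clcn5 had -1.65 ± 0.28, -1.64 ± 0.35, -1.18 ± 0.25, -1.33 ± 0.30 and -1.74 ± 0.40, Clcn5 at -0.46 without mixed cells. Cpt1a (mitochondrial fatty acid import), Samsn1, Arid5b, Rsu1 and Trim14 had 1.15 ± 0.30, 1.00 ± 0.27, 0.81 ± 0.23, 1.00 ± 0.30 and 1.02 ± 0.35.

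Of 7552 genes tested in B-like cells edgeR called 0; 246 had an unadjusted p under 0.05, against 378 by chance, the smallest adjusted p was 0.282, and DESeq2 called 0. With the batch as a block edgeR called 2, both lower: Abtb2, and Agbl1 (-1.60), which was chosen after its value was seen. The same fit made 8 false calls in simulated data without a batch effect. In the real libraries 403 genes had an unadjusted p under 0.05 with the block, above the number by chance. Camera called 11 of 24 lists (4 higher, 7 lower, and 0 with an estimated correlation). The 4 higher lists are not described here. Monocyte markers, of another cell type, were among the called lists and could not be tested without mixed cells. Mixed cells made up 6.12% and 3.65% of B-like cells in double Tg replicates 1 and 2 and 3.51% and 4.65% in single Tg. With the block the integrated stress response was lost (adjusted p = 0.0575), and the inflammatory and ribosomal protein lists were called lower (0.0215 and 0.0416). Without double Tg replicate 1, single Tg replicate 1, double Tg replicate 2 and single Tg replicate 2 edgeR called 48, 14, 16 and 59 genes.

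**Figure D3:**
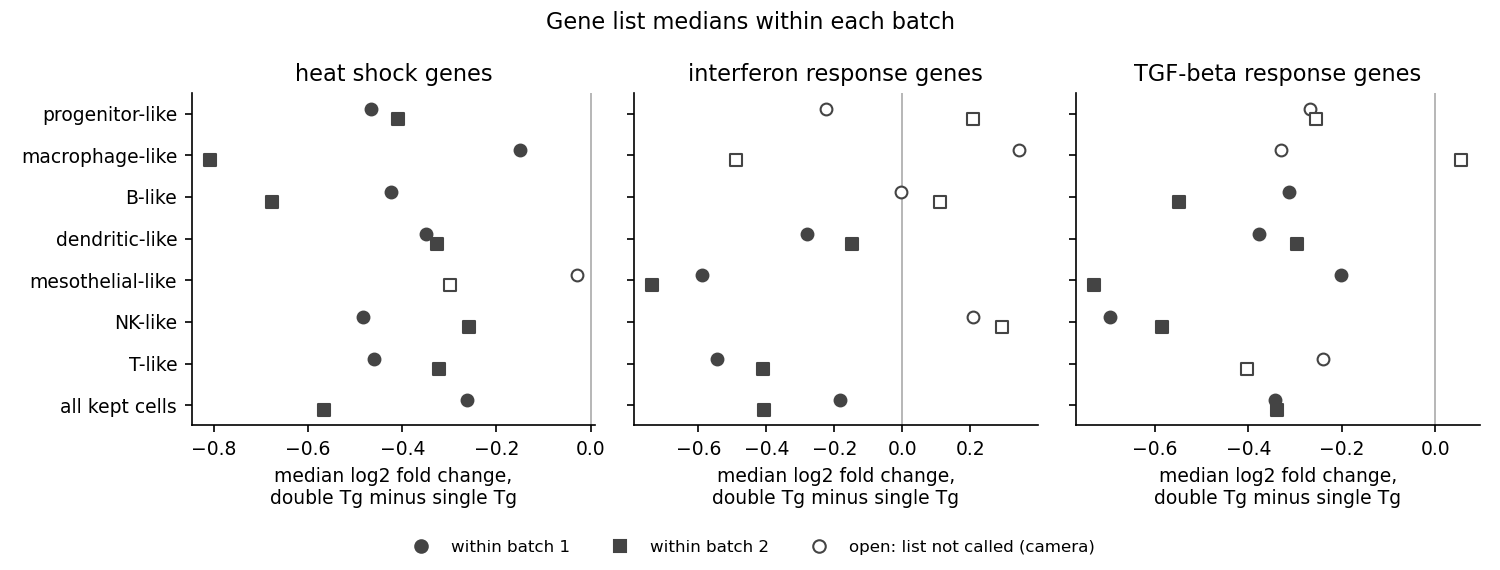
Median log2 fold change, double Tg minus single Tg, of 3 gene lists (panels) within batch 1 (circles) and batch 2 (squares) in the 7 tested classes and all kept cells; open symbols mark lists that camera did not call. The heat shock medians are negative in both batches in every class shown, from -0.03 in batch 1 mesothelial-like cells to -0.81 in batch 2 macrophage-like cells.

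In the sums of all kept cells, which also move with the class shares, macrophage markers rose as a group, 21 of 27 positive with a median of 0.50 (camera adjusted p = 1.8e-07, and adjusted p = 0.711 with an estimated correlation). Plasma-cell markers rose too, 9 of 9 positive with a median of 1.15 (camera adjusted p = 7.6e-07, and adjusted p = 0.711 with an estimated correlation). The first was at 0.0595 without single Tg replicate 2, the second at 0.0927 without single Tg replicate 1 and 0.218 without double Tg replicate 2. Mesothelial markers fell, 16 of 17 negative with a median of -0.80 (camera adjusted p = 4.5e-06, and adjusted p = 0.786 with an estimated correlation), with 0.0658 without double Tg replicate 1 and a turn to the higher side without single Tg replicate 2 (0.567). Heat shock genes fell, 10 of 10 negative with a median of -0.42 (camera adjusted p = 1.3e-05, and adjusted p = 0.711 with an estimated correlation; 0.601 without single Tg replicate 2). TGF-beta response genes fell, 11 of 13 negative with a median of -0.34 (camera adjusted p = 0.00211, and adjusted p = 0.711 with an estimated correlation; 0.860 without single Tg replicate 2). Interferon response genes fell too, 15 of 20 negative with a median of -0.31 (camera adjusted p = 0.0384, and adjusted p = 0.786 with an estimated correlation). That list turned to the higher side without double Tg replicate 1 (0.504) and without single Tg replicate 2 (0.104). Chil3 had 8.46 and 6.66 CPM in double Tg against 1.26 and 1.26 CPM in single Tg (2.58 ± 0.33), and Mmp12 29.7 and 15.1 CPM against 2.00 and 5.33 CPM. The mast-cell protease Cma1 had 71.6 and 39.0 CPM against 12.9 and 20.3 CPM, Plin2 182 and 159 CPM against 113 and 84.2 CPM, and Il23r 0.73 ± 0.19. Inmt and Fmo2 had -1.24 ± 0.23 and -1.17 ± 0.29, Gpc3, a heparan sulfate proteoglycan, 123 and 123 CPM against 228 and 231 CPM, Ctgf -0.90 ± 0.17 and Areg (amphiregulin) -1.18 ± 0.30.

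Of 17505 genes tested in the sums of all kept cells edgeR called 0; 422 had an unadjusted p under 0.05, against 875 by chance, and DESeq2 called 13 (6 higher, 7 lower), among them Chil3, Mmp12, Saa3 and Cma1 higher and Gpc3 and Inmt lower. In simulated data with the spread of the real libraries DESeq2 made 64 false calls here. Camera called 18 of 53 lists (10 higher, 8 lower; 0 with an estimated correlation) and 22 with the batch as a block. The block added LPS receptor signalling on the higher side and mural, epithelial and epididymal markers on the lower side (adjusted p = 0.0334, 0.0347, 0.0387 and 2.3e-05). Without single Tg replicate 1 edgeR called 4 genes, and 0 without each of the other libraries.

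Whether genotype acted differently in macrophage-like and progenitor-like cells was tested with a class by genotype term over 14183 genes. EdgeR called 1 gene, Igkc, the kappa light chain of antibodies (chromosome 6, 70726435 to 70726966), whose effect in macrophage-like cells exceeded that in progenitor-like cells by 2.84 on the log2 scale (adjusted p = 0.0243), while 625 genes had an unadjusted p under 0.05, against 709 by chance. In the separate fits of the 2 classes the effects were 4.03 and 0.92. The call rests on single cells in the double Tg libraries as described above: without mixed cells edgeR called 0 genes. Igkc was at an adjusted p of 0.0857 by edgeR without double Tg replicate 2. DESeq2 called 3 genes, the fit with class by batch terms in place of the library 0, and edgeR called 8, 164, 0 and 174 without double Tg replicate 1, single Tg replicate 1, double Tg replicate 2 and single Tg replicate 2.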

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

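The tests of explanations in this part were all chosen after the results were seen; the class by genotype test was planned.

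Igkc stood out because its genotype effects in macrophage-like and progenitor-like cells differed, by 2.84 on the log2 scale (SE 0.301, edgeR adjusted p = 0.0243; Igkc was higher in both double Tg libraries than in both single Tg libraries in macrophage-like cells). Free antibody RNA spread over droplets is argued against: in the double Tg libraries 1 macrophage-like cell held 89.9% of the class's Igkc UMIs in replicate 1, and 1 cell held 95.9% in replicate 2. Igkc is not among the markers that define mixed cells, yet those 2 cells carried 6 and 5 other B or plasma markers, each present in at most 5% of the class. Without mixed cells the difference was 0.0766 (SE 0.281, edgeR adjusted p = 1). Droplets that hold a macrophage together with a plasma or B cell may therefore account for the call. Such cells were not more frequent in double Tg: there were 2 and 1 in double Tg replicates 1 and 2 and 2 and 4 in single Tg. The cell with the most Igkc held 2183 and 5457 of its UMIs in double Tg against 110 and 96 in single Tg. Whether such pairs form in the tissue or during preparation was not tested, and no biological explanation was tested.

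Class II antigen presentation genes in mesothelial-like cells had a median log2 fold change of 3.39 over Cd74, H2-Aa, H2-Ab1 and H2-Eb1. Free RNA is argued against, since 4 cells held 93.1% and 89.4% of these UMIs in double Tg replicates 1 and 2. Without mixed cells the median was 0.855 (0.411 to 1.49 over the 4 genes; 1.18 and 0.598 in batches 1 and 2), so droplets that also hold a myeloid cell may account for most of it. For the remainder, a difference in the mesothelial cells themselves cannot be told apart from chance or from undetected mixed droplets: camera gave an adjusted p of 1.4e-06 at the preset correlation and 0.417 with an estimated one, with 4 libraries.

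T-like cells passed the threshold in 302 genes with the batch as a block, with a median log2 fold change of 0.866 in the direction of the call (interquartile range 0.673 to 1.17). Mixed cells are argued against as the whole source, since the median was 0.853 (0.654 to 1.15) without them. The number of calls still fell from 302 to 61, all 61 among the 302. Droplets holding a T and an NK cell are not called mixed, so they are not covered by this. Cluster 3 held more of the T-like cells in double Tg in both batches (1.54 and 1.78 times, exact permutation p = 0.333), while clusters 14 and 16 went opposite ways in the batches. Within cluster 3 the median was 0.398 (0.190 to 0.747) over the 234 of these genes tested there. Within the other clusters it was 0.403 (0.156 to 0.722) over 218. Both were at most 46.6% of the class median, which is over all 302 genes and was not taken over the same 234 or 218. A different mix of T clusters may therefore make up a large part of these calls. In these 2 parts 214 of the 234 genes and 194 of the 218 kept the direction of the class. That was favoured by the choice of genes, which were called in the sums of the same cells. The other clusters were also pooled, and their mix was not the same: cluster 9 made up 14.3% of T-like cells in double Tg and 20.7% in single Tg. Whether a difference remains within single clusters is therefore not decided. With the block 1 gene passed within cluster 3 and 35 within the other clusters, of which 1 and 23 were among the 302. A genotype effect on the share of cluster 3 stays open and cannot reach an exact permutation p below 0.333 with 2 mice per genotype.

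Hemoglobin-rich barcodes, which the comparisons leave out, made up 26.8% ± 11.4 (SD, n = 2) of the double Tg barcodes and 17.2% ± 3.87 of the single Tg barcodes. Per library the shares were 18.7% (exact binomial 95% interval 17.1 to 20.5) in double Tg replicate 1, 14.4% (12.6 to 16.4) in single Tg replicate 1, 34.9% (32.9 to 36.9) in double Tg replicate 2 and 19.9% (18.4 to 21.4) in single Tg replicate 2.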

How the results depend on the processing

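The settings with mixed cells removed, at least 1000 genes per cell, hemoglobin-rich and low-gene barcodes kept, cells above 100000 UMIs removed, and T cluster 3 or the other T clusters alone were chosen after the results were seen; the others were set before the data were examined. Except where the setting itself names it (fewer cells, libraries or genes), the cause was not tested. Among single genes 2367 values under other settings kept their direction and side of the threshold, 295 kept the direction and newly passed, 8 kept it and no longer passed, and 19 changed sign. Many of these genes were named for the same sign in both batches, and few passed in the main test. Keeping direction and side was therefore favoured by the choice of genes. Among the called lists 196 values stayed, 97 no longer passed and 10 changed direction. Among shares 228 stayed, 1 newly passed and 47 changed sign.

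DESeq2 called 3 genes in progenitor-like, 21 in macrophage-like, 41 in dendritic-like, 41 in mesothelial-like and 9 in T-like cells, 13 in all cells, and 3 for the class by genotype term. Without a filter on low counts edgeR called 211 in progenitor-like, 198 in macrophage-like, 41 in B-like, 328 in mesothelial-like, 15 in NK-like and 159 in T-like cells, and 125 for the class by genotype term. In macrophage-like cells it called 1 with a mitochondrial limit of 10% and 2 with equal cells per library.

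The batch as a block (replicate block) gave edgeR calls of 2 genes in B-like, 40 in mesothelial-like, 24 in NK-like and 302 in T-like cells in place of 0, 0, 0 and 2. For the class by genotype term a fit with class by batch terms in place of the library called 0 in place of 1, which changes 2 terms at once. With the block 481 genes in NK-like and 403 in B-like cells had an unadjusted p under 0.05, above 343 and 378 by chance, against 277 and 246 without it. The other classes and all cells stayed on the same side of chance. The block also moved the list calls given with each class; it changed no other call. Shares under the block that changed sign were lymphatic endothelial-like cells (0.10 on the log2 scale) and progenitor subclusters 10 (-0.534), 4 (0.167) and 8 (0.078).

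With an estimated correlation camera called 0 lists in progenitor-like, macrophage-like, B-like, dendritic-like, mesothelial-like, NK-like and T-like cells and 0 in all cells; fry called 1 in macrophage-like and 2 in mesothelial-like cells and 0 in the others. Without mixed cells camera called 12 lists in mesothelial-like and 7 in T-like cells, and 7 called lists could not be tested: B in progenitor-like and dendritic-like, T and proliferation in macrophage-like, monocyte in B-like, proliferation in mesothelial-like and class II in NK-like cells. Without mixed cells edgeR called 0 genes in T-like cells and 0 for the class by genotype term. Without the batch as a block it called 0 within T cluster 3 and 0 within the other T clusters, and with the block 1 and 35.

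Single log2 fold changes that changed sign were, without mixed cells, Il1b in progenitor-like (-0.096), Ighm in macrophage-like cells (-0.152) and Cd74 in NK-like cells (0.605). With doublets kept they were Cd74 (-0.132) and H2-Aa (-0.217) in progenitor-like cells. With classes from marker scores they were Ighm (-0.43), Igkc (-0.262) and Il6 (0.052) in macrophage-like cells, and at resolution 0.5 H2-Eb1 (0.025) there. In T-like cells they were Tnfsf11 (-0.222) and Auts2 (-0.8) outside cluster 3 and Setbp1 (0.627) and Ptger4 (0.368) within it.

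Log2 fold changes of shares changed sign with TMM over classes in B-like (0.203), ILC2-like (0.15), T-like (0.18), lymphatic endothelial-like (0.466) and progenitor-like cells (0.052), and in progenitor subclusters 0 (0.015), 4 (0.224) and 8 (0.367). With limma they did so in lymphatic endothelial-like cells (1.04) and subclusters 10 (-0.78), 4 (0.207) and 8 (0.111). The NK-like share changed sign with doublets kept (-0.045), at resolution 2 (-0.091), with marker scores (-0.035) and with hemoglobin-rich barcodes kept (-0.211). The lymphatic endothelial-like share did so with a mitochondrial limit of 10% (0.016) and with at least 1000 genes (0.013). At resolution 0.5 edgeR called 1 class share, that of plasma-like cells (adjusted p = 0.0350).

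Leaving out 1 library leaves 1 in its genotype, which is then assumed to vary like the other genotype. The numbers of called genes then ranged from 0 to 1218 in progenitor-like (399 without single Tg replicate 1, 1218 without single Tg replicate 2), 0 to 67 in macrophage-like, 14 to 59 in B-like, 5 to 186 in dendritic-like, 34 to 110 in mesothelial-like, 1 to 52 in NK-like and 1 to 235 in T-like cells. They ranged from 0 to 4 in all cells and from 0 to 174 for the class by genotype term.

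The numbers of called lists then ranged from 8 to 22 in progenitor-like cells (14, 22, 16 and 8 without double Tg replicate 1, single Tg replicate 1, double Tg replicate 2 and single Tg replicate 2). In the same order they were 12, 12, 12 and 12 in macrophage-like, 15, 9, 4 and 9 in B-like, 4, 8, 11 and 3 in NK-like and 6, 9, 7 and 5 in T-like cells. Crispld2 ranged from -0.80 to 0.42 in progenitor-like, -0.54 to 0.044 in mesothelial-like and -0.54 to 0.17 in all cells, positive only without single Tg replicate 2. Among other genes Il1b ranged from -0.57 to 4.04 and C2 from -1.04 to 0.17 in progenitor-like cells, and Cd163 from -1.54 to 0.32 in macrophage-like cells. In NK-like cells Cd74 ranged from -3.11 to 1.42 and H2-Aa from -3.47 to 0.32, and in B-like cells mt-Atp8 from -1.78 to 0.082.

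The camera adjusted p of lists that changed direction ranged from 1.2e-14 to 0.792 for immediate early genes and 0.000214 to 0.935 for TGF-beta response genes in B-like cells, and 1.9e-05 to 0.792 for interferon response genes in dendritic-like cells. For the inflammatory list in macrophage-like cells it ranged from 9.2e-05 to 0.707, for mitochondrially encoded genes in B-like cells from 6.1e-06 to 0.936 and for class II genes in NK-like cells from 2.0e-13 to 0.384. In all cells it ranged from 5.4e-07 to 0.504 for interferon response genes and 2.7e-20 to 0.567 for mesothelial markers.

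Log2 fold changes of shares ranged from -1.13 to 0.47 (B-like), -0.94 to 0.64 (ILC2-like), -0.40 to 0.62 (NK-like), -0.55 to 0.13 (T-like), -0.14 to 0.65 (dendritic-like), -2.62 to 1.49 (epididymal-like), -0.90 to 0.20 (lymphatic endothelial-like), -1.20 to 1.04 (neutrophil-like), -0.48 to 0.062 (progenitor-like) and -0.061 to 1.04 (proliferating). Among progenitor subclasses they ranged from -0.35 to 1.45 (Dpp4-like), and by subcluster from -0.70 to 0.21 (0), -2.71 to 0.94 (10), -2.72 to 0.18 (2), -1.09 to 1.71 (4), -1.45 to 0.13 (6), -0.63 to 0.98 (8) and -1.27 to 0.43 (9).

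Depth limits the calls less than the spread between libraries does. With counting noise alone edgeR recovered 86% of simulated 2-fold and 98% of 4-fold changes in progenitor-like cells and 85% and 96% in T-like cells. With the spread of the real libraries it recovered 2% and 62%, and 38% and 89%.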

Other observations

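The camera tests of the heat shock list were planned, apart from the one without mixed cells; that test and the other observations in this part were chosen after the results were seen.

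Heat shock genes were lower as a group in double Tg cells in 6 of the 7 tested classes by camera at the preset correlation, and in 0 with an estimated correlation. The classes come from the same 4 mice and are not independent of each other. In progenitor-, macrophage- and T-like cells the call was lost when certain single libraries were left out. Their median log2 fold changes in batches 1 and 2 were -0.47 and -0.41 in progenitor-like, -0.15 and -0.81 in macrophage-like, -0.42 and -0.68 in B-like, -0.35 and -0.33 in dendritic-like, -0.48 and -0.26 in NK-like and -0.46 and -0.32 in T-like cells. In mesothelial-like cells, where the list was not called (camera adjusted p = 0.25), they were -0.03 and -0.30; without mixed cells it was called there (0.0349). Whether the classes differ in this was not tested, and genotype and the handling of each tissue cannot be separated for these genes with 1 mouse of each genotype per batch.

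Cluster 3 made up 48.3% ± 7.23 (SD, n = 2) of T-like cells in double Tg and 29.4% ± 7.28 in single Tg, 1.54 and 1.78 times as much in batches 1 and 2 (exact permutation p = 0.333). Il17a (chromosome 1, 20730905 to 20734496), singled out after its values were seen, had a log2 fold change of 2.23 over the T-like class and 1.47 within cluster 3 in the fit with the batch as a block.

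The 13 germ cell genes of a list written after these transcripts were noticed (among them Prm1, Prm2, Tnp1 and Odf1) had 25, 1629, 182 and 1563 UMIs in the kept cells of double Tg replicate 1, single Tg replicate 1, double Tg replicate 2 and single Tg replicate 2. In single Tg replicate 1, 1139 and 464 of them lay in 2 cells with 180893 and 226695 UMIs in all. Epididymal-like cells held 0, 1139, 164 and 1527.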
